A study of Homo sapiens with 12 samples.

How the data were processed

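Single-nucleus RNA sequencing was made from post-mortem middle temporal gyrus of 12 individuals, 6 with Alzheimer's disease (AD) and 6 without it (HC), with 1 library per donor. Per the labels' protocols, nuclei were isolated through sucrose by ultracentrifugation, libraries were made with the 10x Genomics Chromium Single Cell 3′ kit of chemistry version 3, and sequencing was on an Illumina NovaSeq6000. Groups come from the sample titles, and the design text gives individuals with and without AD. The labels used here give no batch and no sex, so the comparison of sexes that the series title names was not analysed here, and sex was not inferred. No paired analysis was possible because the labels give no link between an AD and an HC donor. Replicate numbers only name the libraries.

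The deposited matrices hold raw UMI counts per gene and barcode, whole numbers that the authors had not normalised. Reads were counted with Cell Ranger 3.0.2 on GRCh38 per the submitters' processing notes, while the file headers name Cell Ranger 3.1.0; which version made the counts was not resolved. Barcodes had been filtered to called nuclei by the authors with settings not given in the sources used here, and the lowest barcode holds 310 UMIs. Whether counting used the strand of the reads is not stated, and this was not tested for antisense genes. The matrices hold 81975 barcodes and 33538 genes, of which 33456 IDs matched GENCODE 29 (Ensembl 94, GRCh38), the source of all coordinates.

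Barcodes with at least 300 detected genes and at most 10 percent mitochondrial UMIs were kept, which removed 839 for few genes and 2485 for mitochondrial share, some for both, and left 79270. Doublets were scored per sample with Scrublet, and the highest-scoring 0.8 percent per 1000 nuclei were removed, 5195 in all, which left 74075 nuclei. XIST, TSIX and Y-linked genes (102) were left out of all fits and tables. Counts were log-normalised and reduced to 2000 variable genes and 30 principal components without integration across donors, and clustered with 15 neighbours and the Leiden method at resolution 1 (seed 0), which gave 38 clusters. Clusters were named from 13 lists of cell type markers and 10 of neuron subclass markers. The cell types were excitatory and inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells, mural cells (pericytes or smooth muscle) or fibroblasts, T cells, B or plasma cells, erythroid cells and ependymal cells. No cluster was named as the last 3 of these. A name needed at least 3 markers with a level of 0.25 or more of the highest cluster; this rule was set after the clusters were seen. All cell type names are therefore rebuilt and mean "-like" nuclei. Pericyte or smooth muscle and fibroblast nuclei shared 1 cluster and are treated as 1 type. In all, 4 clusters with 2172 nuclei stayed unnamed.

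The donor was the replicate throughout. Shares of named nuclei per sample were compared by two-sided exact permutation tests of the group means, over all 924 splits of 12 samples or all 462 splits of 11, with Benjamini-Hochberg adjustment over types, or over subclasses with at least 50 nuclei of the class in a sample. For expression, counts were summed per sample and type over samples with at least 20 nuclei of the type. Each type with at least 4 samples per group was fitted alone with edgeR 4.0.16 (TMM normalisation, filterByExpr, quasi-likelihood test), with genes called at an adjusted p under 0.05 within the type. Endothelial-like and T-cell-like nuclei were too few to fit. The 24 lists of pathway and state genes were tested with camera at a preset correlation of 0.01 (limma 3.58.1) when at least 5 members were tested, adjusted over all list and type pairs. An estimated correlation and fry served as alternatives. A difference of a list's AD effect between types was tested by exact permutation of the within-donor difference of mean log2 CPM. The marker lists were also tested inside every type, as signs of RNA from other cells. Some markers are also members of the lists of astrocyte homeostasis, homeostatic microglia, myelin, glutamate, presynaptic and GABA genes. Such a list and its markers move together in part by construction.

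All lists, groups, tests and naming rules were fixed before the data were examined, except where stated. The tests of explanations in the closing section were set up after the called genes were seen, and so was the list of 13 glucocorticoid targets, which leaves out called genes and was written before its own values were looked at. The rule names, per type, up to 10 genes higher and 10 lower by smallest adjusted p, leaving out clone-named transcripts, which are counted. It adds called members of each list (up to 4), the AD risk genes APOE, CLU, BIN1, TREM2, APP, MAPT, SORL1 and PICALM in types that express them, GFAP in astrocytes, SPP1, P2RY12 and CD163 in microglia, and SST, PVALB, VIP and VGF in inhibitory neurons. Where fewer than 5 genes were called, those with the 5 smallest p are named as not called. Other list members are given as examples, those with the smallest p of a called list, and so were chosen after their values were seen.

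Alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, voom with sample quality weights, log2 median UMIs as a covariate, a minimum of 500 genes, no doublet removal, Leiden resolution 0.5 (25 clusters), centred log-ratios of counts plus 0.5, a prior count of 5, each sample left out in turn, and AD 1 left out for its shallow depth. After the data were seen, 1 more was added: leaving out AD 3, HC 2 and HC 4, the libraries that hold over 90 percent of a cluster of at least 100 nuclei. Calls were also counted over 60 splits of the samples, the real one included. The 3 gene tests were tested on simulated data made from these counts with 200 changed genes per type; edgeR recovered 60 percent of 2-fold and 97 percent of 4-fold changes in oligodendrocyte-like nuclei, 27 and 88 percent in microglia-like nuclei, and 7 and 71 percent in mural or fibroblast-like nuclei. Between 1.68 and 10.1 percent of edgeR's calls there were false. No 2 libraries of a group held copies of the same counts: over 30 pairs the lowest chi-square per gene was 24.2. Total UMIs per library ran from 2480857 to 125892743, and how far the low depth of AD 1 limits calls was not tested. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and R 4.3.3 were used.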

Results

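Nuclei from the middle temporal gyrus, a neocortical area of the temporal lobe, were profiled by single-nucleus RNA sequencing in 6 donors with Alzheimer's disease (AD 1 to AD 6) and 6 donors without it (HC 1 to HC 6). The deposited matrices held between 1301 barcodes (HC 3) and 11207 barcodes (HC 5). Total UMIs per library were 2480857 in AD 1, 70665243 in AD 2, 75523159 in AD 3, 30630839 in AD 4, 28840223 in AD 5 and 14091239 in AD 6. In the HC group they were 34059887 in HC 1, 111398418 in HC 2, 11023390 in HC 3, 33252998 in HC 4, 125892743 in HC 5 and 72661880 in HC 6. After filtering and doublet removal, 1521, 6867, 9144, 4394, 5608 and 5262 nuclei were kept in AD 1 to AD 6, and 5196, 9382, 1222, 5405, 10182 and 9892 in HC 1 to HC 6. The comparison of AD with HC asks which cell types, genes and gene groups of this cortex differ in the disease. All cell type names were rebuilt from marker genes and stand for "-like" nuclei.

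Library quality leaned towards the HC group without passing the test. The mean per library of nuclei kept was 5466 ± 2540 in AD and 6880 ± 3557 in HC (SD, n = 6 each; exact permutation test, adjusted p = 0.446). Median UMIs per nucleus were 3729 ± 2042 against 5349 ± 1763 and median genes 1842 ± 823 against 2411 ± 592, and the mitochondrial share of UMIs was 1.98 ± 1.25% against 1.19 ± 0.539% (adjusted p = 0.277 for each of these, exact permutation tests). AD 1 had the lowest median, 735 UMIs, and the highest mitochondrial share, 4.38%. The differences in UMIs and mitochondrial share, -1620 and 0.784 points, were -1021 and 0.305 without AD 1, and the former was -1052 without HC 5. The difference in median genes, -569, was -310 without AD 1, and that in nuclei kept, -1414, ran from -2545 without HC 3 to -625 without AD 1.

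The share of microglia-like nuclei was the one cell type share that differed at an unadjusted p under 0.05. These immune cells of the brain made up 8.46 ± 2.23% of named nuclei in AD and 4.14 ± 2.36% in HC, a difference of 4.31 percentage points (n = 6 each; exact permutation p = 0.0130, adjusted p = 0.117), which does not pass. Oligodendrocyte-like nuclei, the myelin-forming cells, held 43.2 ± 20.3% in AD and 29.7 ± 20.2% in HC. Excitatory-neuron-like nuclei held 20.1 ± 13.7% against 30.9 ± 13.999%, and astrocyte-like nuclei 6.86 ± 4.49% against 11.2 ± 6.71% (adjusted p = 0.614 for each of these 3 types, exact permutation tests). Inhibitory-neuron-like nuclei were at 13.2 ± 8.56% against 15.1 ± 4.17%, and oligodendrocyte precursors at 6.61 ± 2.66% against 7.57 ± 1.41%. Endothelial-like nuclei were at 0.512 ± 0.352% against 0.419 ± 0.294%, mural or fibroblast-like nuclei at 0.850 ± 0.583% against 0.833 ± 0.536%, and T-cell-like nuclei at 0.207 ± 0.156% against 0.195 ± 0.112%. The adjusted p of these last 5 types lay between 0.793 and 0.961 by the exact test. As centred log-ratios, the microglia-like share differed by 1.24 on the log2 scale and passed (exact permutation, adjusted p = 0.0195). Its difference in percentage points was 4.28 without AD 1 and 4.10 without AD 3, HC 2 and HC 4. The oligodendrocyte-like difference, 13.5 points, was 7.45 without AD 6, the excitatory one, -10.7, was -7.16 without AD 1 and -7.12 without HC 3, and the astrocyte one, -4.34, was -2.61 without HC 2 and -0.698 without AD 3, HC 2 and HC 4. With 1 donor left out the precursor difference, -0.967, ran from -1.98 to -0.486.

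**Figure D1:**
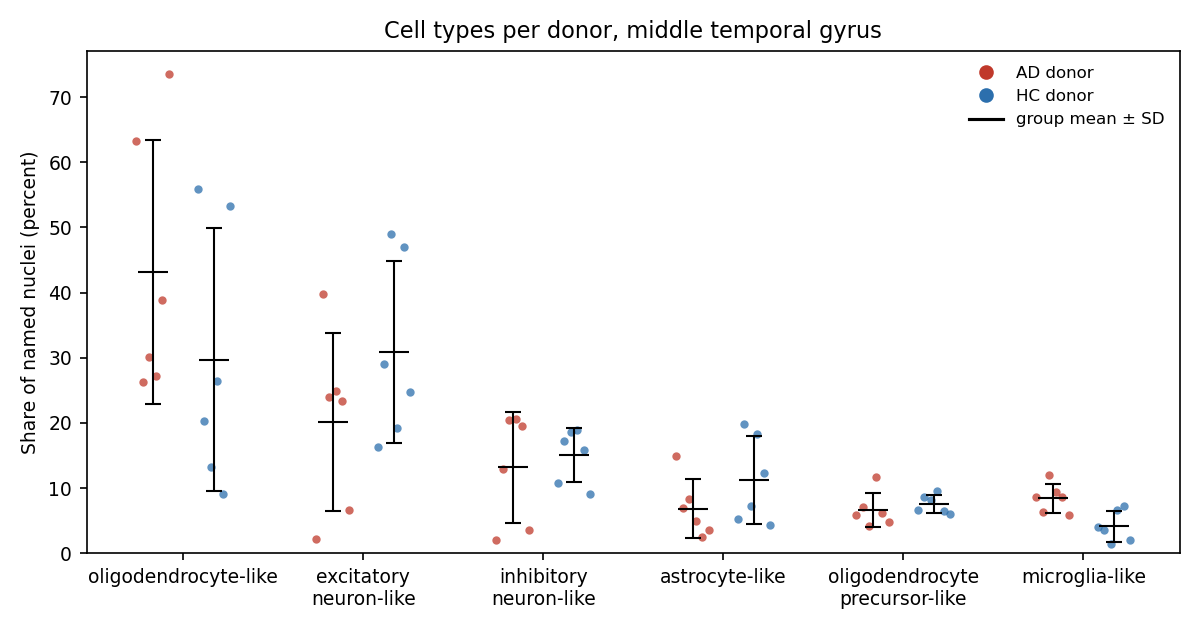
Each point is the share of one donor's named nuclei, in percent (vertical axis), in the 6 most abundant rebuilt cell types (horizontal axis), with AD and HC donors in separate colours, bars at the group means and whiskers of 1 SD. Microglia-like nuclei average 8.46% in AD and 4.14% in HC, and the groups overlap in each type shown.

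Among neurons, the upper-layer CUX2 subclass was smaller and the middle-layer RORB and inhibitory LAMP5 subclasses larger in AD at unadjusted p under 0.05, and none passed after adjustment. These shares were compared over 5 AD and 6 HC donors, because AD 1 held fewer than 50 nuclei of the class. CUX2-named nuclei made up 34.0 ± 12.7% of excitatory-neuron-like nuclei in AD and 55.0 ± 15.0% in HC, a difference of -21.1 points (exact permutation p = 0.0390, adjusted p = 0.1299). RORB-named nuclei made up 33.6 ± 4.19% against 21.8 ± 7.87%, a difference of 11.8 points (exact permutation p = 0.0238, adjusted p = 0.119). LAMP5-named nuclei made up 19.4 ± 7.68% of inhibitory-neuron-like nuclei against 11.6 ± 3.45%, a difference of 7.78 points (exact permutation p = 0.0173, adjusted p = 0.119). Without AD 3 the LAMP5 difference was 9.53 points and passed (exact permutation, adjusted p = 0.0476), and without AD 6 it was 4.52 points. The SST subclass was at 11.2 ± 4.05% against 16.4 ± 6.33%, VIP at 33.3 ± 3.52% against 35.8 ± 3.14%, PVALB at 20.01 ± 4.86% against 18.5 ± 6.11%, and PAX6 or SNCG at 16.2 ± 5.72% against 17.7 ± 7.65%. Deep-layer FEZF2-named nuclei were at 5.98 ± 2.57% against 5.39 ± 1.57%, THEMIS-named nuclei at 3.65 ± 2.57% against 2.24 ± 0.876%, and excitatory nuclei without a subclass at 22.8 ± 6.15% against 15.5 ± 8.29%. The adjusted p of these 7 lay between 0.294 and 0.706 by the exact test. The VIP difference, -2.54, ran from -4.00 to -1.61 with 1 donor left out, and the THEMIS difference, 1.41, was 0.341 without AD 6. The CUX2, RORB and LAMP5 differences were -20.4, 13.7 and 8.31 points without AD 3, HC 2 and HC 4.

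**Figure D2:**
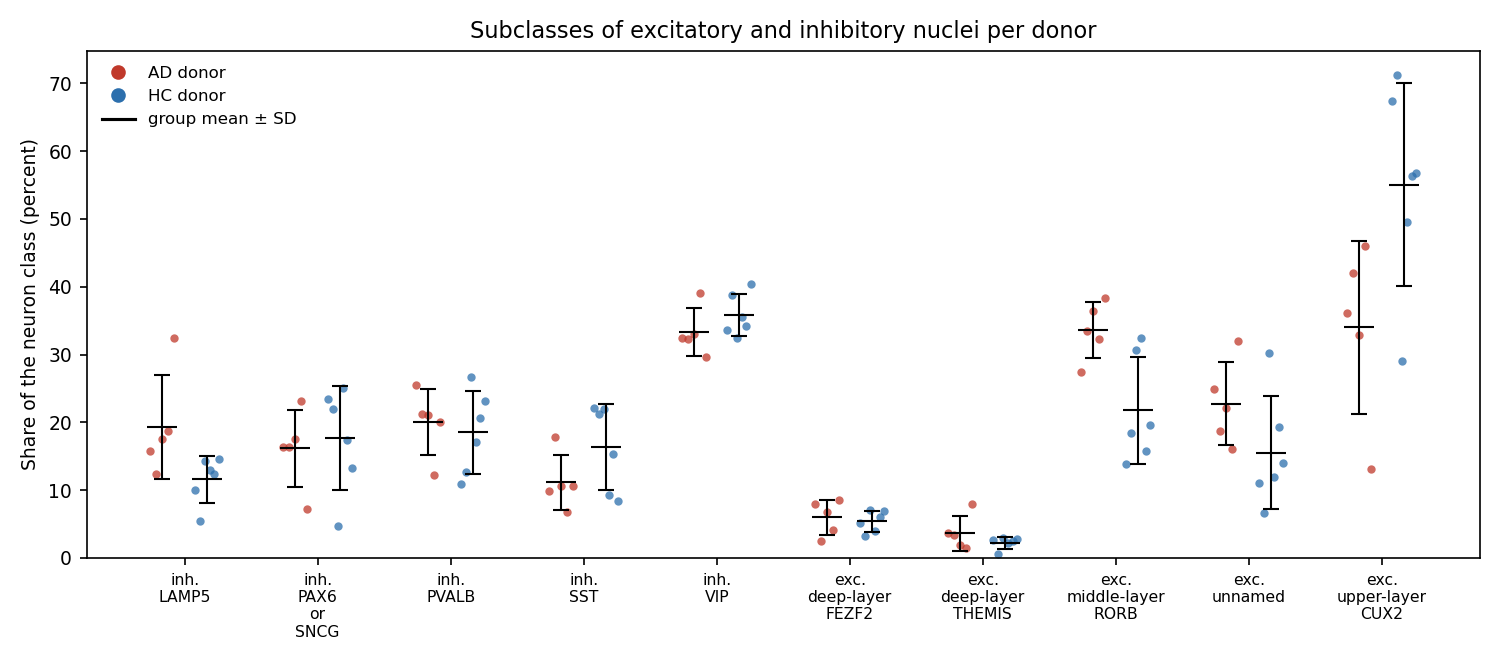
Each point is one donor's share of a neuron subclass in percent of its excitatory or inhibitory nuclei (vertical axis), by subclass (horizontal axis), for 5 AD and 6 HC donors, with bars at the group means and whiskers of 1 SD. CUX2-named nuclei average 34.0% in AD and 55.0% in HC, and RORB-named nuclei 33.6% and 21.8%.

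In excitatory-neuron-like nuclei, 4 genes rose and 7 fell in AD, of 17013 tested (edgeR, 6 AD and 6 HC donors), while DESeq2 called 223 and voom 1146. ADAMTS2 (ENSG00000087116, GRCh38 chromosome 5, 179110851 to 179345430), which encodes a procollagen-processing protease, rose by 1.85 ± 0.27 (log2 fold ± SE, adjusted p = 0.0146), from 12.4 ± 3.89 to 45.0 ± 14.9 CPM (UMI counts scaled to a common library total, mean ± SD). PRELP (ENSG00000188783, chromosome 1, 203475828 to 203491352), a leucine-rich proteoglycan of the matrix, rose by 1.96 ± 0.30 from 1.39 ± 0.216 to 5.93 ± 2.09 CPM (edgeR, adjusted p = 0.0150). SMARCD3, a subunit of SWI/SNF chromatin remodellers, rose by 1.02 ± 0.18 and MACROD1, which removes ADP-ribose from proteins, by 0.94 ± 0.16 (edgeR, adjusted p = 0.0490 each). SPRY4-AS1 (ENSG00000231185, chromosome 5, 142325293 to 142672001), an antisense transcript, fell by 2.73 ± 0.41 on the log2 scale from 66.3 ± 40.1 to 9.78 ± 4.997 CPM (edgeR, adjusted p = 0.0150). Whether its count holds reads of the opposite strand was not tested. The other 6 lower genes carry clone names. All 5 named genes lay on their side of the HC mean in 6 of 6 AD donors, while the amyloid precursor gene APP (0.06 ± 0.13) and the tau gene MAPT (0.01 ± 0.17) did not pass. Microglia markers were higher in these nuclei in AD (mean log2 fold 0.96 over 6 markers, camera adjusted p = 5.58e-05; adjusted p = 0.293 with an estimated correlation). The CUX2-named share was lower by 21.1 points at the same time, and the clone-named AC093607.1, LINC02296 and AC109779.1, all among the 6 that fell, are leading transcripts of the CUX2-named clusters. The count of 11 became 8 without AD 1, 95 without AD 2, 6 without AD 3, 4 without AD 4, 3 without AD 5, 82 without HC 3 and 51 without HC 4. It was 16 without AD 3, HC 2 and HC 4 together, of which 6 were among the 11. ADAMTS2 lost its call without AD 5 (adjusted p = 0.0606), SPRY4-AS1 without AD 3, AD 4 or AD 5 (up to 0.0694) and PRELP without AD 4, AD 5, HC 1 or HC 6 (up to 0.0793). SMARCD3 and MACROD1 kept theirs without AD 2, HC 3 or HC 4 and lost it in the other 9 runs with 1 donor left out (adjusted p up to 0.126 and 0.146, edgeR).

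Of 23 gene lists tested in excitatory-neuron-like nuclei, 6 were higher and 2 lower in AD (camera). Of their 173 members, 0 passed over all genes by edgeR (27 at an unadjusted p under 0.05), 4 by DESeq2 and 22 by voom, and 6 passed adjusted over the list alone. Mitochondrially encoded transcripts were higher in 13 of 13 (mean 1.03, adjusted p = 1.58e-06; adjusted p = 0.682 with an estimated correlation), with MT-ND3 at 1.51 ± 0.56, beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC, and 0 of the 13 passed adjusted over the list alone (7 at an unadjusted p under 0.05). Heat shock and chaperone genes were higher in 18 of 21 (mean 0.39, adjusted p = 2.51e-05; adjusted p = 0.682 with an estimated correlation), with STIP1 at 0.71 ± 0.25 and DNAJB6 at 0.50 ± 0.15. The list of disease-associated microglia was higher in 12 of 15 members (mean 0.45, adjusted p = 0.00419; adjusted p = 0.416 with an estimated correlation). Its 3 members past the threshold adjusted over the list alone were SPP1 at 2.84 ± 0.67, B2M at 1.26 ± 0.27 and, lower, LPL at -1.66 ± 0.34. Homeostatic microglia genes were higher in 5 of 7 (mean 0.48, adjusted p = 0.0304; adjusted p = 0.682 with an estimated correlation), with CSF1R at 1.13 ± 0.36, SLC2A5 at 0.84 ± 0.29 and P2RY12 at 0.81 ± 0.30, all 3 past the threshold adjusted over the list alone. Both of these lists moved with the microglia markers (mean 0.96). Myelin genes were higher in 18 of 20 (mean 0.57, adjusted p = 0.000813; adjusted p = 0.720 with an estimated correlation) beside oligodendrocyte markers at 0.48. Cholesterol synthesis genes were higher in 19 of 22 (mean 0.31, adjusted p = 0.0116; adjusted p = 0.773 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were lower in 45 of 47 (mean -0.35, adjusted p = 0.0428; adjusted p = 0.866 with an estimated correlation), opposite to the mitochondrially encoded ones. Glutamate receptor and postsynaptic genes were lower in 23 of 28 (mean -0.14, adjusted p = 0.0496; adjusted p = 0.720 with an estimated correlation), with GRIK1 at -0.98 ± 0.27. Neuropeptides did not pass as a list by camera (mean -0.35, adjusted p = 0.518) and did by fry in either direction (adjusted p = 0.00558), and 7 of their 15 members passed adjusted over the list alone. The myelin call ended without AD 6 (mean 0.18, adjusted p = 0.0855) and its mean was 1.11 without HC 6. The cholesterol call ended without AD 3 (-0.01) or HC 4 (0.23), and without AD 3, HC 2 and HC 4 the mean was -0.11. The oxidative phosphorylation call ended without AD 2 or AD 4 (-0.30), AD 5 or AD 6 (-0.31), HC 1 (-0.36) or HC 3 (0.10), and its mean was -0.59 without AD 3. The homeostatic microglia call ended without AD 2 (0.47), AD 3 (0.49) or HC 1 (0.43). The glutamate call ended without AD 1 or AD 6 (-0.12), AD 3 (-0.08), HC 1 (-0.11), or HC 2, HC 4 or HC 5 (-0.13).

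In inhibitory-neuron-like nuclei, neuropeptide genes were lower as a list in AD, and no single gene passed over all genes. The list had 16 of 19 members below 0 (mean log2 fold -0.82, camera adjusted p = 4.12e-06, and 0.682 with an estimated correlation). Adjusted over the list alone, 8 members passed. VGF (ENSG00000128564, chromosome 7, 101162509 to 101165593), the precursor of several secreted peptides, was at 1.10 ± 1.93 CPM in AD and 45.5 ± 51.6 in HC (log2 fold -4.82 ± 0.90, edgeR adjusted p = 0.139 over all genes). VIP (ENSG00000146469, chromosome 6, 152750798 to 152759765), vasoactive intestinal peptide, was at 21.2 ± 12.8 against 84.0 ± 49.8 CPM (-1.67 ± 0.35, edgeR adjusted p = 0.178). TAC3 was at -1.69 ± 0.37 and the stress peptide CRH at -3.05 ± 0.75, and neither passed over all genes by edgeR, nor did somatostatin (SST, -1.01 ± 0.78) and parvalbumin (PVALB, -0.11 ± 0.44). SST was at -2.33 without AD 2 and -0.41 without HC 1. Of 14885 genes tested by edgeR 0 passed, 1274 had an unadjusted p under 0.05, and DESeq2 called 36 and voom 49. The other genes with the smallest p, not called, were NAT16 (-2.90), SPRY4-AS1 (-2.45, antisense as above), SHC3 (-0.83) and PDE10A (-1.13), with adjusted p between 0.123 and 0.139. APP (-0.03) and MAPT (0.08) did not differ detectably. Mitochondrially encoded transcripts were higher in 13 of 13 (mean 0.83, adjusted p = 6.80e-09; adjusted p = 0.682 with an estimated correlation) beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC, and nuclear-encoded oxidative phosphorylation genes lower in 46 of 47 (mean -0.41, adjusted p = 3.12e-06; adjusted p = 0.720 with an estimated correlation). Myelin genes were higher in 19 of 20 (mean 0.56, adjusted p = 1.75e-07; adjusted p = 0.682 with an estimated correlation), with MBP at 0.56 ± 0.24, beside oligodendrocyte markers at 0.55 (adjusted p = 0.00366; adjusted p = 0.606 with an estimated correlation). GABA genes were lower in 17 of 21 (mean -0.16, adjusted p = 0.0190; adjusted p = 0.682 with an estimated correlation), led by the GABA-synthesising enzyme GAD1 at -0.69 ± 0.23. Of the members of the 5 lists called in this type, 0 passed over all genes by edgeR, 3 by DESeq2 and 1 by voom. The markers that define inhibitory neurons were lower too (mean -0.37, adjusted p = 0.00454; adjusted p = 0.471 with an estimated correlation). The count of 0 stayed 0 without AD 1 (1412 genes at an unadjusted p under 0.05) and became 7 without AD 2, 2 without HC 4, and 77 without AD 3, HC 2 and HC 4. The GABA call ended without AD 1 (-0.13), AD 3 (-0.17), HC 1 (-0.12) or HC 2 (-0.15). The myelin mean was 0.25 without AD 6 and 1.06 without HC 6, and the oxidative phosphorylation mean -0.69 without AD 3 and -0.18 without HC 3.

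In astrocyte-like nuclei, NPNT rose and NDRG4 fell in AD. NPNT (ENSG00000168743, chromosome 4, 105894775 to 106004027), an extracellular matrix protein that binds integrins, rose by 3.38 ± 0.40 on the log2 scale (edgeR, adjusted p = 0.00257), from 6.62 ± 4.07 to 73.0 ± 31.1 CPM. NDRG4 (ENSG00000103034, chromosome 16, 58462846 to 58513628) fell by 1.62 ± 0.24 from 133 ± 30.8 to 43.0 ± 14.2 CPM (edgeR, adjusted p = 0.0186). Both lay on their side of the HC mean in 6 of 6 AD donors. The third gene, the clone-named AC008056.1, fell by 2.59 and is named after its values were seen. ANGPT1 (2.17), LMNTD1 (2.56), C1orf87 (2.80), COL21A1 (2.73) and SLC39A11 (1.73) had the next smallest p and were not called (adjusted p 0.0624 to 0.0687). APOE, a lipid carrier and AD risk gene, was at 445 ± 234 CPM in AD and 1020 ± 432 in HC (-1.19 ± 0.32, edgeR adjusted p = 0.195), and the filament gene GFAP at 2015 ± 1071 against 644 ± 633 (1.64 ± 0.56, edgeR adjusted p = 0.311). MAPT (0.32; 0.13 without AD 3 and 0.88 without HC 2) and CLU (-0.19; -0.03 without HC 1) did not pass. NPNT passed with any 1 donor left out (adjusted p at most 0.0102), while NDRG4 did not pass without AD 4, AD 5, AD 6, HC 1 or HC 2 (up to 0.0820). DESeq2 called 144 genes and voom 11. The count of 3 of 12382 genes was 3 without AD 1, 24 without AD 2, 7 without AD 3, 5 without HC 4, 6 without HC 5, and 2 without AD 3, HC 2 and HC 4. Of the astrocyte-like nuclei, clusters of 713, 729 and 1667 nuclei came almost alone from AD 3, HC 4 and HC 2.

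Of 22 lists tested in astrocyte-like nuclei, 2 were higher and 7 lower in AD. Of their 228 members, 0 passed over all genes by edgeR (34 at an unadjusted p under 0.05), 6 by DESeq2 and 0 by voom, and 13 passed adjusted over the list alone. Astrocyte homeostasis genes, which serve glutamate and potassium uptake among other tasks, were lower in 16 of 19 (mean -0.54, adjusted p = 1.61e-06; adjusted p = 0.416 with an estimated correlation). ALDH1A1 (-1.62 ± 0.34), ATP1B2 (-1.16 ± 0.25), EDNRB (-1.04 ± 0.28) and glutamine synthetase, GLUL (-0.98 ± 0.28), were among 6 past the threshold adjusted over the list alone. Reactive astrocyte genes were higher in 10 of 16 (mean 0.63, median 0.16, adjusted p = 4.35e-05; adjusted p = 0.682 with an estimated correlation), with SYNM (1.65 ± 0.37), complement C3 (2.38 ± 0.58), S100A10 (2.44 ± 0.68) and GFAP past the threshold adjusted over the list alone. Their mean was 0.04 without AD 3, 0.22 without HC 2, 0.29 without HC 5 and 1.24 without HC 4. GABA genes were lower in 12 of 16 (mean -0.48, adjusted p = 0.0116; adjusted p = 0.682 with an estimated correlation), with the receptor subunit GABRA4 at -2.38 ± 0.56. Ribosomal protein genes were lower in 64 of 69 (mean -0.40, adjusted p = 2.90e-08; adjusted p = 0.682 with an estimated correlation) and oxidative phosphorylation genes in 33 of 47 (mean -0.15, adjusted p = 0.00365; adjusted p = 0.720 with an estimated correlation). Hypoxia response genes were lower in 18 of 20 (mean -0.49, adjusted p = 0.00419) and cholesterol synthesis genes in 17 of 22 (mean -0.40, adjusted p = 0.00473; adjusted p = 0.682 with an estimated correlation for both), with VEGFA at -1.54 ± 0.62 and INSIG1 at -1.36 ± 0.45. Metallothioneins were lower in 7 of 7 (mean -0.66, adjusted p = 0.0496; adjusted p = 0.682 with an estimated correlation), and mitochondrially encoded transcripts higher in 11 of 12 (mean 0.53, adjusted p = 0.0211; adjusted p = 0.776 with an estimated correlation), beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC. The mitochondrial call ended without AD 1 (0.04), AD 6 or HC 5 (0.40), HC 4 (0.45) or HC 6 (0.35), and its mean was 1.04 without HC 2. The metallothionein call ended without AD 2 (-0.61), AD 4 (-0.56), AD 6 (-0.66), HC 1 (-0.74), HC 3 or HC 5 (-0.59) or HC 4 (-0.30). The GABA call ended without AD 1 (-0.41), AD 3 (-0.40), HC 2 (-0.34) or HC 5 (-0.30), and the cholesterol call without HC 2 (-0.24). Without AD 3 the means of cholesterol, hypoxia and oxidative phosphorylation genes were -0.76, -0.86 and -0.46, and the last was -0.10 without AD 2, AD 5 or AD 6. Without AD 3, HC 2 and HC 4 the ribosomal mean was -0.81, and the GABA and hypoxia calls ended (-0.33 and -0.45).

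In microglia-like nuclei, 4 genes fell in AD and none rose, of 8922 tested (edgeR, 6 AD and 5 HC donors). SOX5 (ENSG00000134532, chromosome 12, 23529500 to 24562544), a transcription factor of the SoxD group, fell by 2.39 ± 0.30 on the log2 scale (edgeR, adjusted p = 0.00659), from 262 ± 116 to 49.9 ± 10.7 CPM. RASGEF1C (ENSG00000146090, chromosome 5, 180100791 to 180209153), which carries a Ras guanine nucleotide exchange domain, fell by 2.82 ± 0.45 from 776 ± 453 to 108 ± 49.5 CPM (edgeR, adjusted p = 0.0433). Both were below the HC mean in 6 of 6 AD donors. The clone-named AC008050.1 and LINC02057 fell by 4.74 and 3.21 and are named after their values were seen. PLEKHG5 (-2.10), TLN2 (-1.255), CECR2 (-2.40), ITGA4 (3.18) and EYA2 (2.41) came next and were not called (adjusted p 0.0653 to 0.0986). APOE was at 1124 ± 385 CPM in AD and 528 ± 142 in HC (1.08 ± 0.28, edgeR adjusted p = 0.219). The homeostatic receptor P2RY12 (-0.79), the scavenger receptor CD163 (1.73), SPP1 (0.93), TREM2 (0.40), PICALM (0.35), SORL1 (-0.31) and BIN1 (-0.23) did not pass either. SPP1 was at 0.0026 without AD 3 and 2.23 without HC 4, and with 1 donor left out TREM2 ran from 0.19 to 0.71, PICALM from 0.22 to 0.50 and SORL1 from -0.51 to -0.12. Markers of excitatory neurons (mean -0.88, adjusted p = 0.00841; adjusted p = 0.471 with an estimated correlation) and of astrocytes (mean -1.23, adjusted p = 0.00366; adjusted p = 0.471 with an estimated correlation) were lower in these nuclei in AD. In HC, SOX5 was at 9.21% of its highest level in any other type, while RASGEF1C was highest in microglia-like nuclei. SOX5 passed with any 1 donor left out and RASGEF1C in 3 of 11 such runs (adjusted p up to 0.124). The count of 4 was 2 without AD 1, AD 2, AD 5 or AD 6, 9 without HC 4 or HC 6, and 13 without HC 5. It was 0 by edgeR without AD 3, HC 2 and HC 4 (771 genes at an unadjusted p under 0.05), with SOX5 at adjusted p = 0.0904. In all donors DESeq2 called 96 genes and voom 4. A cluster of 1083 microglia-like nuclei came to 91.1% from AD 3 and a cluster of 304 to 99.7% from HC 2.

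Of 22 lists tested in microglia-like nuclei, 3 were higher and 4 lower in AD. Of their 112 members, 0 passed over all genes by edgeR (35 at an unadjusted p under 0.05), 6 by DESeq2 and 0 by voom, and 16 passed adjusted over the list alone. Genes of disease-associated microglia, a state described around amyloid plaques, were higher in 16 of 21 (mean 0.70, adjusted p = 8.33e-08; adjusted p = 0.303 with an estimated correlation). GPNMB (2.07 ± 0.52), APOE, the phosphatase PTPRG (2.24 ± 0.60), MITF (1.02 ± 0.28) and lipoprotein lipase, LPL (1.90 ± 0.60), were among 6 past the threshold adjusted over the list alone. Homeostatic microglia genes were lower in 9 of 14 (mean -0.28, adjusted p = 0.0496; adjusted p = 0.682 with an estimated correlation), with NAV3 (-0.98 ± 0.26) past the threshold adjusted over the list alone. Mitochondrially encoded transcripts were higher in 12 of 12 (mean 1.15, adjusted p = 1.08e-09; adjusted p = 0.682 with an estimated correlation) beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC, and heat shock genes in 18 of 19 (mean 0.62, adjusted p = 0.000581; adjusted p = 0.682 with an estimated correlation). Glutamate receptor and postsynaptic genes were lower in 23 of 24 (mean -0.80, adjusted p = 7.35e-09), presynaptic genes in 15 of 17 (mean -0.62, adjusted p = 0.000272) and astrocyte homeostasis genes in 4 of 5 (mean -0.89, adjusted p = 0.0464); adjusted p = 0.682 with an estimated correlation for each. The glutamate transporter SLC1A2, an astrocyte gene, was at -2.50 ± 0.49. These neuron and astrocyte lists moved with the neuron and astrocyte markers (means -0.88 and -1.23). The heat shock call ended without AD 3 (0.25). The homeostatic call ended without AD 3 (-0.24), AD 5 (-0.22), AD 6 (-0.27), HC 1 (-0.13) or HC 5 (-0.31), and with DESeq2's size factors (-0.29). The astrocyte homeostasis call ended without AD 2 (-0.85), AD 3 (-0.96), AD 4 (-0.92), AD 5 (-0.87) or HC 4 (-0.53). Without AD 3, HC 2 and HC 4 the disease-associated mean was 0.77, and the calls of the other 3 ended (0.15, -0.29 and -0.44 in this order).

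In oligodendrocyte-like nuclei, 18 genes rose and 12 fell in AD, of 14121 tested (edgeR, 6 AD and 6 HC donors). QDPR (ENSG00000151552, chromosome 4, 17460261 to 17512234), which regenerates the cofactor tetrahydrobiopterin, rose by 1.21 ± 0.18 on the log2 scale from 549 ± 91.4 to 1270 ± 302 CPM (edgeR, adjusted p = 0.0334). The transcription factor KLF15 (ENSG00000163884, chromosome 3, 126342635 to 126357442) rose by 1.33 ± 0.21 from 22.8 ± 3.56 to 59.5 ± 16.9 CPM (edgeR, adjusted p = 0.0344). NFKBIA (ENSG00000100906, chromosome 14, 35401511 to 35404749), the inhibitor that holds NF-kB in the cytoplasm, rose by 2.15 ± 0.36 from 15.3 ± 7.16 to 71.6 ± 29.1 CPM (edgeR, adjusted p = 0.0361). The amino acid transporter SLC38A2 (1.63 ± 0.28), LPL (3.29 ± 0.60), FMO5 (2.17 ± 0.35), METTL7A (2.00 ± 0.35), LHFPL2 (2.02 ± 0.36), CDKL1 (1.25 ± 0.23) and FANCC (1.31 ± 0.24) rose with the same adjusted p of 0.0361. GREB1L fell by 1.68 ± 0.26 on the log2 scale (adjusted p = 0.0334). TEX9 (-1.79), the antisense LMCD1-AS1 (-1.31, strand not tested) and the late-endosome GTPase RAB7B (-3.04) fell (edgeR, adjusted p = 0.0361 each). The fatty acid elongase ELOVL2 (-2.32), the cadherin CDH4 (-1.55) and HES4 (-2.95) fell with the same adjusted p. The potassium channel KCNH8 (-0.93), HHAT (-1.46) and FBXO7 (-0.98) fell too. Each named gene lay on its side of the HC mean in 6 of 6 AD donors. MAPT (0.49 ± 0.20, adjusted p = 0.239), APP (-0.31), PICALM (-0.19; -0.06 without HC 4) and BIN1 (-0.01) did not pass. Markers of excitatory neurons (mean -0.95, adjusted p = 0.00454; adjusted p = 0.471 with an estimated correlation) and astrocytes (mean -1.02, adjusted p = 0.0129; adjusted p = 0.735 with an estimated correlation) were lower in these nuclei in AD. Some called genes are leading transcripts of oligodendrocyte clusters filled unevenly by donors (MID1IP1 and the clone-named AC009063.2, both higher, are named after their values were seen). These are QDPR and AC009063.2 in a cluster of 3315 nuclei, 55.6% from AD 6, both with MID1IP1 in one of 2795, 43.4% from AD 5, and KCNH8 in one of 3990, 56.6% from HC 6. The count of 30 was 396 without AD 2, 3 without HC 1 and 2 without HC 4, and it was 0 by edgeR with any 1 of the other 9 donors left out (1787 to 2504 genes at an unadjusted p under 0.05). Without AD 3, HC 2 and HC 4 it was 2, of which 1 was among the 30. In all donors DESeq2 called 528 and voom 171, with 29 and 27 of the 30 among them. With 1 donor left out, in every run that tested it, the fold of each of the 20 named genes kept its direction, and RAB7B reached -3.64 without AD 2.

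**Figure D3:**
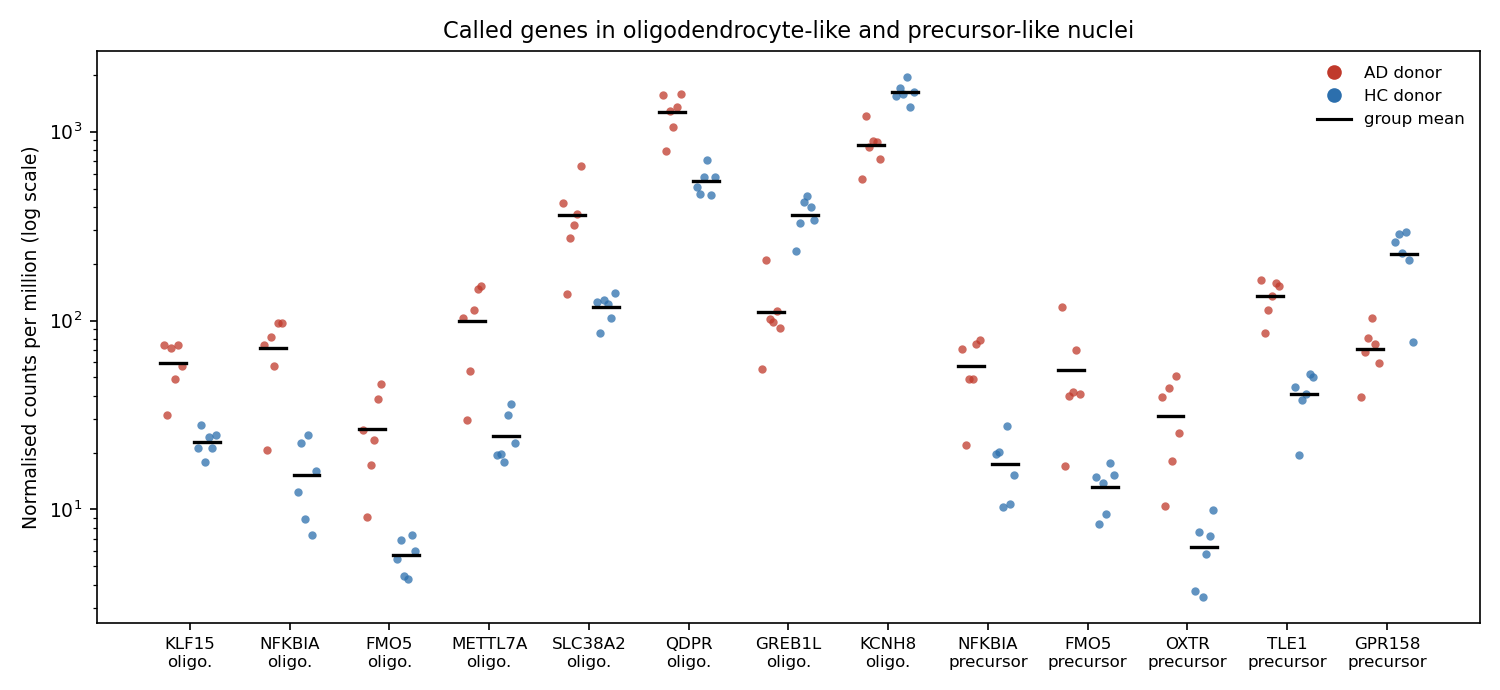
Each point is one donor's expression in CPM on a log axis (vertical), for genes called in oligodendrocyte-like nuclei or in their precursors (horizontal), with AD and HC donors in separate colours and bars at the group means. QDPR averages 1270 CPM in AD and 549 in HC in oligodendrocyte-like nuclei, and TLE1 135 and 40.7 in the precursors.

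Of 23 lists tested in oligodendrocyte-like nuclei, 5 were higher and 4 lower in AD. Of their 231 members, 1 passed over all genes by edgeR (NFKBIA), 13 by DESeq2 and 1 by voom, and 20 passed adjusted over the list alone. NF-kB and cytokine response genes were higher in 6 of 7 (mean 0.74, adjusted p = 0.00696; adjusted p = 0.682 with an estimated correlation), with NFKBIA, the apoptosis inhibitor BIRC3 (2.08 ± 0.61) and NFKB2 (1.11 ± 0.41) past the threshold adjusted over the list alone. Heat shock genes were higher in 18 of 21 (mean 0.44, adjusted p = 0.000196; adjusted p = 0.682 with an estimated correlation), of which 8 passed adjusted over the list alone, among them the HSP90 partners AHSA1 (0.82 ± 0.24) and FKBP4 (0.95 ± 0.28) and the chaperone HSP90AB1 (0.71 ± 0.23). Cholesterol synthesis genes were higher in 18 of 22 (mean 0.32, adjusted p = 0.00792; adjusted p = 0.682 with an estimated correlation), with DHCR7 at 1.42 ± 0.36. Unfolded protein response genes were higher in 16 of 20 (mean 0.27, adjusted p = 0.0264; adjusted p = 0.720 with an estimated correlation), with PDIA4 at 0.62 ± 0.27. Ribosomal protein genes were higher in 67 of 71 (mean 0.40, adjusted p = 3.56e-08; adjusted p = 0.682 with an estimated correlation). Glutamate receptor and postsynaptic genes were lower in 26 of 28 (mean -0.68, adjusted p = 2.51e-05), presynaptic genes in 26 of 27 (mean -0.60, adjusted p = 0.000395), GABA genes in 15 of 19 (mean -0.76, adjusted p = 0.00312) and astrocyte homeostasis genes in 12 of 16 (mean -0.99, adjusted p = 0.00303). The adjusted p was 0.682 with an estimated correlation for each of these 4, which moved with the neuron and astrocyte markers (means -0.95 and -1.02). GRIA3 (-1.13 ± 0.28), CAMK2A (-1.79 ± 0.49), SLC1A2 (-2.31 ± 0.55) and ATP1B2 (-2.03 ± 0.51) were among those past the threshold adjusted over the list alone. Myelin genes did not pass as a list (mean -0.07, adjusted p = 0.634), nor did mitochondrially encoded transcripts (mean 0.26, adjusted p = 0.472). The NF-kB call ended without HC 6 (0.61, adjusted p = 0.0523), the cholesterol call without AD 6 (0.18), and the presynaptic call without HC 2 (-0.25). The unfolded protein response call ended without AD 3 (0.18), AD 5 (0.24), HC 2 (0.21), HC 3 (0.23) or HC 4 (0.19). Without HC 2 the ribosomal, glutamate and GABA means were 0.26, -0.41 and -0.42. Without AD 3, HC 2 and HC 4 the calls of ribosomal (0.10), unfolded protein response (0.00), GABA (-0.44) and astrocyte homeostasis genes (-0.32) ended, and the cholesterol mean was 0.58.

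In oligodendrocyte precursors, 12 genes rose and 1 fell in AD, of 12986 tested (edgeR, 6 AD and 6 HC donors), while DESeq2 called 70 and voom 46. TLE1 (ENSG00000196781, chromosome 9, 81583683 to 81689305), a transcriptional corepressor, rose by 1.69 ± 0.23 on the log2 scale (edgeR, adjusted p = 0.00934), from 40.7 ± 11.7 to 135 ± 30.1 CPM. NFKBIA rose here as well, by 1.59 ± 0.30 from 17.3 ± 6.60 to 57.3 ± 21.7 CPM (edgeR, adjusted p = 0.0498), and so did FMO5 (1.84 ± 0.34). AJAP1 (1.35 ± 0.22), the mitochondrial glutamate carrier SLC25A18 (1.37 ± 0.23), the sialic acid lyase NPL (1.07 ± 0.18), the lipase MGLL, which degrades an endocannabinoid (1.29 ± 0.22), the oxytocin receptor OXTR (2.11 ± 0.36) and the kinesin KIF19 (1.93 ± 0.34) rose, each with an adjusted p of 0.0320. TOB2 rose by 1.00 ± 0.19, and GPR158, an orphan receptor, fell by 1.59 ± 0.27 on the log2 scale. Another 1 of the 13 carries a clone name. Each named gene lay on its side of the HC mean in 6 of 6 AD donors, and APP (-0.17; -0.0040 without HC 4) did not pass. Markers of excitatory neurons were lower in these nuclei (mean -0.59, adjusted p = 0.0129; adjusted p = 0.471 with an estimated correlation). TLE1 passed with any 1 donor left out (adjusted p at most 0.0453), and the other named genes in 1 to 4 of 12 such runs. The count of 13 was 1 without AD 1, AD 4, AD 5, AD 6, HC 1 or HC 5, 2 without HC 2 or HC 6, 3 without AD 3, 37 without AD 2, 26 without HC 4, and 8 without AD 3, HC 2 and HC 4 (4 of the 13 among them).

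Of 22 lists tested in oligodendrocyte precursors, 4 were higher and 2 lower in AD. Of their 150 members, 0 passed over all genes by edgeR (19 at an unadjusted p under 0.05), 1 by DESeq2 and 1 by voom, and 6 passed adjusted over the list alone. Mitochondrially encoded transcripts were higher in 11 of 12 (mean 0.83, adjusted p = 1.25e-07; adjusted p = 0.682 with an estimated correlation), with MT-ND3 at 1.19 ± 0.30, beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC, and heat shock genes in 19 of 20 (mean 0.47, adjusted p = 1.76e-05; adjusted p = 0.682 with an estimated correlation), with HSP90AA1 at 0.61 ± 0.22. Their means were 0.46 without AD 1 and 0.25 without AD 3, respectively. Metallothioneins were higher in 6 of 6 (mean 0.32, adjusted p = 0.0179; adjusted p = 0.682 with an estimated correlation), with MT3 (0.78 ± 0.25) past the threshold adjusted over the list alone. Ribosomal protein genes were higher in 62 of 70 (mean 0.32, adjusted p = 0.00232; adjusted p = 0.849 with an estimated correlation). This turned without AD 3 (-0.05) and without AD 3, HC 2 and HC 4 together, where they were lower (mean -0.22, adjusted p = 0.000219), and the call ended without HC 2 (0.20). Presynaptic genes were lower in 20 of 27 (mean -0.19, adjusted p = 0.0141) and GABA genes in 12 of 15 (mean -0.38, adjusted p = 0.0205; adjusted p = 0.682 with an estimated correlation for both), beside the lower neuron markers (mean -0.59). GABRB2 was at -1.70 ± 0.50 and the vesicle protein SYN2 at -0.52 ± 0.17. The GABA call ended without HC 2 (-0.20) or HC 5 (-0.25) and the presynaptic call without HC 2 (-0.08) or HC 5 (-0.15). The metallothionein call ended without AD 1 (0.27), AD 3 (0.21), AD 5 (0.13), HC 2 (0.14) or HC 5 (0.20), and the mean was 1.06 without HC 4. Without AD 3, HC 2 and HC 4 the metallothionein and heat shock means were 0.70 and 0.22, and the GABA and presynaptic calls ended (-0.26 and -0.12).

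In mural or fibroblast-like nuclei, the cells around vessels, 1 gene rose of 2497 tested (edgeR, 6 AD and 4 HC donors). SHISA6 (ENSG00000188803, chromosome 17, 11241263 to 11564063), an auxiliary subunit of AMPA receptors, rose by 2.28 ± 0.35 on the log2 scale from 110 ± 57.2 to 564 ± 114 CPM (edgeR, adjusted p = 0.0453), in 6 of 6 AD donors. ANKRD36C (-1.67), KCNIP4 (-2.80), BTG1 (1.93), ANK2 (-1.69) and AK5 (-1.995) came next and were not called (adjusted p 0.0565 to 0.102), and APP was at 0.04. Of 12 lists tested, 5 were higher and 2 lower, with 5 of their 74 members past the threshold adjusted over the list alone and 0 over all genes by edgeR (16 at an unadjusted p under 0.05), 5 by DESeq2 and 3 by voom. Glutamate receptor genes (11 of 11, mean -1.28, adjusted p = 6.21e-06) and presynaptic genes (6 of 6, mean -1.35, adjusted p = 0.00565) were lower, with GRM5 at -2.02 ± 0.58. Neuron markers were too few to test here, so RNA from neurons stays open. Ribosomal protein genes (23 of 24, mean 0.66, adjusted p = 1.46e-05), heat shock genes (8 of 9, mean 0.82, adjusted p = 0.0171) and hypoxia response genes (4 of 5, mean 0.64, adjusted p = 0.0496) were higher, with the stress gene DDIT4 at 2.19 ± 0.60. The adjusted p was 0.682 with an estimated correlation for these 5. Astrocyte homeostasis genes were higher in 8 of 8 (mean 0.92, adjusted p = 0.00232; adjusted p = 0.416 with an estimated correlation), with NDRG2 at 1.72 ± 0.42, and mitochondrially encoded transcripts in 10 of 11 (mean 0.48, adjusted p = 0.0250; adjusted p = 0.755 with an estimated correlation), beside a mean mitochondrial share of 1.98% of UMIs in AD and 1.19% in HC. The count of 1 was 0 by edgeR without AD 1 (261 genes at an unadjusted p under 0.05), AD 4, AD 5, AD 6, HC 2 or HC 5, 9 without AD 2, 53 without AD 3, 16 without HC 1, 1 other gene without HC 6, and 23 without AD 3, HC 2 and HC 4. SHISA6 reached an adjusted p of up to 0.148 where it was lost. In all donors DESeq2 called 54 and voom 61. The astrocyte homeostasis call ended without HC 1 (0.63) or HC 6 (0.04). The heat shock call ended without AD 3 (0.64) or HC 2 (0.63), with 0.42 without AD 1. The hypoxia call ended without AD 1 (0.63), AD 2 or AD 5 (0.60) or AD 3 (0.51), with 1.32 without HC 2. The mitochondrial call ended without AD 1 (0.22), AD 3 (0.46), HC 5 (0.28) or HC 6 (0.33), with 0.82 without HC 1 and 0.77 without HC 2. The ribosomal mean was 1.05 without HC 1, 0.35 without HC 2 and 0.40 without HC 5, and without AD 3, HC 2 and HC 4 the ribosomal and heat shock calls ended (0.27 and 0.45).

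**Figure D4:**
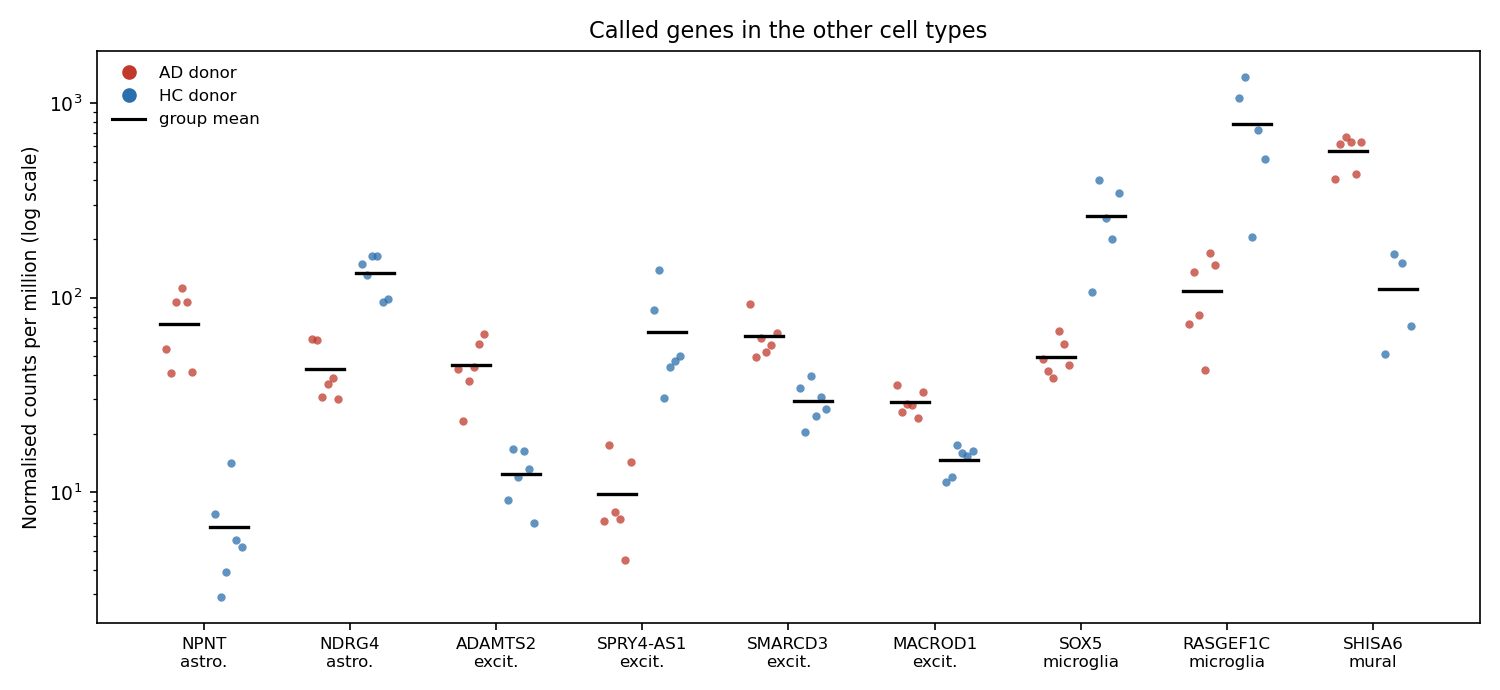
Each point is one donor's expression in CPM on a log axis (vertical), for genes called in the other cell types (horizontal), with AD and HC donors in separate colours and bars at the group means. NPNT in astrocyte-like nuclei averages 73.0 CPM in AD and 6.62 in HC, and SOX5 in microglia-like nuclei 49.9 and 262.

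By camera, the AD risk genes did not pass as a list in any of 7 types (smallest adjusted p = 0.405), and neither did complement and MHC class II (0.244), interferon response (0.141), immediate early genes (0.146), lysosome and autophagy (0.172) or angiogenesis and blood-brain barrier genes (0.105). Across all 24 lists, 145 pairs of list and type were tested with camera and 51 passed, 27 higher and 24 lower, with 58 at an unadjusted p under 0.05. The count was 50 without AD 1 and 45 without AD 3, HC 2 and HC 4, of which 33 were among the 51. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05, smallest adjusted p = 0.303), by fry in one direction 0 (12 unadjusted, smallest adjusted p = 0.143) and by fry in either direction 17. These 17 include the AD risk genes in astrocyte-like (adjusted p = 0.00862), inhibitory-neuron-like (0.0264) and oligodendrocyte-like nuclei (0.00860) and precursors (0.000663, fry), interferon response (0.0166) and angiogenesis genes (0.00229) in excitatory-neuron-like nuclei, and lysosome and autophagy genes in oligodendrocyte-like nuclei (0.00860). Of the 51 calls, 26 were kept with any 1 donor left out. Mitochondrially encoded transcripts were higher in 6 types, beside mean shares of 1.98% of UMIs in AD and 1.19% in HC (4.38% in AD 1). Heat shock genes were higher in 5, and glutamate, presynaptic and GABA genes lower in 4 each.

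Whether a list's change differed between cell types was tested for 207 pairs of types, of which 43 had an exact permutation p under 0.05 and 0 passed after adjustment (39 unadjusted with a prior count of 5). The 5 with the smallest possible p, 0.00216 (exact permutation, adjusted p = 0.0896 each), concerned disease-associated microglia genes and neuropeptides. The AD effect on disease-associated microglia genes was lower in astrocyte-like nuclei than in microglia-like (by -1.12) and excitatory-neuron-like nuclei (-0.79). It was higher in excitatory-neuron-like than in inhibitory-neuron-like nuclei (0.72), and in microglia-like nuclei than in precursors (1.03). The effect on neuropeptides was 1.06 higher in excitatory-neuron-like than in inhibitory-neuron-like nuclei. None passes, but p could not go lower, so this stays undecided.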

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

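The explanations weighed here were chosen after the called genes were seen, and depth as a covariate after its result. Each ± of a median below is over genes, not donors.

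A donor stood apart where its gap to the nearest donor of its group, over the range of the group, passed the 95% critical value of Dixon's test. This held in 24 of the 218 groups tested. Chance gives about 1 in 20 (10.9) if values are normal, which was not tested. The groups share donors, so no excess is shown. AD 2 stood apart 5 times, AD 1 and HC 2 4 each, AD 3 and HC 3 3 each, HC 1 and HC 4 2 each, and AD 6 1. The mean mitochondrial share was 4.38% in AD 1, with the next AD donor at 2.13%. THEMIS-named nuclei made up 0.5257% of the excitatory-neuron-like nuclei of HC 2 (14 of 2663, 95% Wilson interval 0.313 to 0.881%), with the next HC donor at 2.15%. In astrocyte-like nuclei, C1orf87 was at 63.5 CPM in AD 6 (nearest other donor of the group 27.3), APOE at 1859 in HC 1 (1051) and MAPT at 649.8 in HC 2 (207). APP in excitatory-neuron-like nuclei was at 406 CPM in AD 1 (545). In inhibitory-neuron-like nuclei, AD 2 had NAT16 at 1.44 CPM (0.380), VGF at 4.96 (1.00) and SST at 66.4 (18.3), HC 2 had SPRY4-AS1 at 182 (86.6) and HC 3 had PVALB at 26.2 (9.12). In microglia-like nuclei, SPP1 was at 11498 CPM in AD 3 (2011) and at 6069 in HC 4 (1160), and TLN2 at 105 in AD 1 (210). In mural or fibroblast-like nuclei, KCNIP4 was at 667 CPM in HC 1 (2669) and AK5 at 236 in AD 3 (116). In oligodendrocyte-like nuclei, AD 2 had GREB1L at 210.2 CPM (112) and LMCD1-AS1 at 608 (352), AD 3 had MAPT at 985 (604) and AD 1 had BIN1 at 1007 (597). RAB7B was at 0 there in HC 3 (0 of 217685 UMIs, so under 13.8 CPM, the limit of 3 counts; nearest 6.35). In the precursors, AJAP1 was at 55.1 CPM in HC 3 (33.6), SLC25A18 at 28.7 in HC 2 (17.7) and APP at 1097 in HC 4 (675).

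The 11 genes called in excitatory-neuron-like nuclei moved while the share of CUX2-named nuclei was lower by 21.1 points in AD, and a different mix of subclasses as their whole cause would take their folds under 0.5 of their size within CUX2-named nuclei. Over 9959 such nuclei of 5 AD and 6 HC donors, the median ratio of the fold there to that in all excitatory-neuron-like nuclei of these donors was 0.767 ± 0.0911 for the 7 lower genes and 0.834 ± 0.231 for the 4 higher ones, which argues against the mix as the whole cause. In CUX2-named nuclei alone edgeR, the tool run on them, called 0 of 16202 genes (1459 at an unadjusted p under 0.05). The median log2 fold went from -2.39 (median SE 0.328) to -1.80 (0.392) for the lower genes and from 1.43 (0.222) to 0.93 (0.246) for the higher ones, and these smaller folds, wider errors and 1 donor fewer ended the calls (smallest adjusted p = 0.0910, edgeR). PRELP, with a ratio of 0.210, stays open, as do a different mix of finer clusters among the CUX2-named nuclei and the disease itself, which were not tested.

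The 18 genes that rose in oligodendrocyte-like nuclei and the 12 that rose in their precursors did so in a group whose mean mitochondrial share differed by 0.784 points (0.305 without AD 1) and whose median UMIs by -1620 (-1021 without AD 1, -1052 without HC 5), though neither difference passed its test. If RNA quality or depth were the whole cause, their folds would drop under 0.5 of their size with that measure as a covariate; the median ratio over these 30 was 0.922 ± 0.0178 with the mitochondrial share and 0.913 ± 0.0194 with log2 median UMIs, which argues against either. With the mitochondrial share edgeR called 0 genes in each type (2141 and 1080 at an unadjusted p under 0.05), and with depth 0 as well (1647 and 837); the other tools were not run with covariates. In oligodendrocyte-like nuclei the median log2 fold of the 18 went from 1.68 (median SE 0.288) to 1.56 (0.313) and 1.57 (0.280), and in the precursors that of the 12 from 1.48 (0.230) to 1.33 (0.251) and 1.35 (0.24975), so smaller folds, 1 degree of freedom fewer and, except with depth in oligodendrocyte-like nuclei, wider errors ended the calls (smallest adjusted p = 0.0517, edgeR). Depth, RNA quality, the disease and a response to glucocorticoids, weighed below, stay open. So does a different mix of oligodendrocyte clusters, not tested. QDPR, MID1IP1 and AC009063.2 are among the leading transcripts of clusters to which AD 6 or AD 5 gave the most nuclei.

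Markers of excitatory neurons and astrocytes were lower in oligodendrocyte-like and in microglia-like nuclei of AD donors, and free RNA from other cells is a candidate source of these transcripts. Over 11 donors, deviations from the group means in these cell types went together, with r = 0.762 (permutation p = 0.00787, adjusted p = 0.00787; rho = 0.836, permutation p = 0.00330; r = 0.832 without the 2 farthest donors) for the excitatory markers and r = 0.918 (permutation p = 0.00166, adjusted p = 0.00332; rho = 0.909, permutation p = 0.00137; r = 0.816) for the astrocyte markers, 2 relations of 5 genes each, and free RNA needs such values. RASGEF1C, called lower in microglia-like nuclei, was in HC at 776 CPM there, 3206% of its level in the highest other type (24.2), which argues against such RNA as its source. SOX5 was at 262 CPM, 9.21% of its level in astrocyte-like nuclei (2846). It lay above 9 of the 10 markers (median 4.63%, NRGN next at 8.91%). Only SLC1A3 was higher (57.8%), far above the other astrocyte markers (1.16 to 5.45%), so it may not stand for free RNA. With NRGN this close, free RNA and a change within microglia cannot be told apart for SOX5. SLC1A3 is in the astrocyte relation. The disease was not tested apart from free RNA and stays open.

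Other splits of the donors into groups of the same sizes were fitted with edgeR, 60 for each cell type with the real one included. In excitatory-neuron-like nuclei 1 of 60 splits called as many genes as the real one (11, highest other 3), in microglia-like nuclei 2 of 60 (4, highest other 12), in oligodendrocyte-like nuclei 2 of 60 (30, highest other 48) and in the precursors 2 of 60 (13, highest other 60). For these 4 counts the share of drawn splits was under 0.05. Only 60 of the 462 possible splits were drawn per type, without adjustment over the counts, so chance is not excluded. The share did not fall under 0.05 in astrocyte-like nuclei (3 of 60 for a count of 3, highest other 28). The same held in mural or fibroblast-like nuclei (6 of 60 for a count of 1, highest other 130) and inhibitory-neuron-like nuclei (60 of 60 for a count of 0, highest other 323). That 0 of edgeR stands beside 1274 genes at an unadjusted p under 0.05, 36 called by DESeq2 and 49 by voom. Nor is chance excluded for list and type pairs in the 5 types with all 12 donors. The real split gave 35 here, fewer than the calls above, and 29 of 60 matched it (highest other 52). In all types but excitatory-neuron-like and oligodendrocyte-like nuclei, some splits called several times the real count. What those splits share was not tested.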

How the results depend on the processing

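Leaving out AD 3, HC 2 and HC 4 together was chosen after the data were seen. Over 3178 comparisons of a result with an alternative, 2249 kept direction and side of the threshold, 683 kept direction and lost the threshold, 96 passed it anew, 60 changed sign and 90 were counts or values that moved. The 41 calls of a named gene in a type kept their direction in each of 852 comparisons and their threshold in 375. Of 865 comparisons of called lists, 655 kept the call, 206 lost it and 4 changed direction, taken as camera's direction against the other genes; the mean of cholesterol synthesis in excitatory neuron-like nuclei without AD 3, among the 206, also changed sign (-0.013). The 4 measures of depth and quality kept direction and side in 52 of 52. No paired analysis was possible, as donors share no link. Low depth in AD 1 (not tested) and few mural or fibroblast-like nuclei may limit calls. With fewer samples the tests have fewer degrees of freedom, and without a filter more genes are tested; beyond this, the cause was not tested for any value below.

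Counts of called genes are given in the order astrocyte, excitatory, inhibitory, microglia, mural or fibroblast, oligodendrocyte and precursor nuclei, against 3, 11, 0, 4, 1, 30 and 13. They were 3, 8, 0, 4, 0, 30 and 12 with DESeq2's size factors, 23, 40, 6, 62, 269, 125 and 63 with no low-count filter, and 144, 223, 36, 96, 54, 528 and 70 by DESeq2. With voom they were 11, 1146, 49, 4, 61, 171 and 46, and with depth as a covariate 3, 14, 0, 1, 1, 0 and 0. A minimum of 500 genes gave 3, 11, 0, 5, 0, 32 and 13, and no doublet removal 6, 8, 0, 5, 13, 28 and 1. The counts were 3, 8, 0, 2, 0, 0 and 1 without AD 1, and 2, 16, 77, 0, 23, 2 and 8 without AD 3, HC 2 and HC 4, of which 2, 6, 0, 0, 1, 1 and 4 were among those called in all donors. Where edgeR gave 0, at least 191 genes had an unadjusted p under 0.05. With 1 donor left out the counts ran from 2 to 24, 3 to 95, 0 to 7, 2 to 13, 0 to 53, 0 to 396 and 1 to 37, in the same order. The 51 calls of lists became 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 0 by fry in one direction (12).

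Shares that changed sign had not passed. Without doublet removal T-cell-like nuclei differed by -0.000915 points. Without AD 1 endothelial-like nuclei differed by -0.0328 points, inhibitory-neuron-like nuclei by 0.347 and mural or fibroblast-like nuclei by -0.203. Without AD 3, HC 2 and HC 4 these last were at -0.0862, precursors at 0.275, the PAX6 or SNCG subclass at 1.38 and PVALB at -0.633. As centred log-ratios FEZF2 was at -0.188 and microglia-like nuclei passed at 1.24. With 1 donor left out the ranges were -0.0328 to 0.204 for endothelial-like, -3.38 to 0.347 for inhibitory-neuron-like, -0.203 to 0.152 for mural or fibroblast-like and -0.0435 to 0.0398 for T-cell-like nuclei. For the subclasses they were 4.52 to 9.53 for LAMP5, -4.08 to 0.726 for PAX6 or SNCG, -0.0484 to 1.46 for FEZF2 and -0.0489 to 3.44 for PVALB.

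Genes that changed sign had not passed. MAPT in excitatory neuron-like nuclei was at -0.013 with no low-count filter. APP in inhibitory neuron-like nuclei was at 0.034 with voom, 0.0068 with depth as a covariate and 0.0098 without AD 1. APP in mural or fibroblast-like nuclei was at -0.12 with no low-count filter, -0.038 by DESeq2, -0.15 with voom, -0.084 with no doublet removal and -0.28 without AD 3, HC 2 and HC 4. BIN1 in oligodendrocyte-like nuclei was at 0.0043 with DESeq2's size factors, 0.00097 by DESeq2 and 0.0032 with no doublet removal. TREM2 in microglia-like nuclei was at -0.15 without AD 3, HC 2 and HC 4. With 1 donor left out the ranges were -0.066 to 0.13 for MAPT in excitatory neuron-like, -0.059 to 0.022 for APP and -0.012 to 0.17 for MAPT in inhibitory neuron-like, and -0.61 to 0.28 for PVALB there. They were -0.48 to 0.21 for BIN1 in microglia-like, -0.19 to 0.16 for APP in mural or fibroblast-like and -0.21 to 0.063 for BIN1 in oligodendrocyte-like nuclei. Called lists that changed direction were cholesterol synthesis in excitatory neuron-like nuclei (-0.11) and ribosomal proteins in the precursors (-0.22), both without AD 3, HC 2 and HC 4. With 1 donor left out these ran from -0.01 to 0.38 and from -0.053 to 0.43, and oxidative phosphorylation in excitatory neuron-like nuclei from -0.59 to 0.10.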

Other observations

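The genes named in the next 2 paragraphs and the test of glucocorticoid levels per cell type were chosen after the values were seen, and the glucocorticoid list and its test after the called genes were seen. The covariates, left-out donors and relations for that list were added last.

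Among the AD risk genes, which did not pass as a list by camera and passed by fry in either direction in 4 types, the phospholipase gene PLCG2 passed adjusted over the list alone in 4 cell types, and in none over all genes by edgeR. Its level was 121 ± 60.5 CPM in AD and 49.9 ± 22.5 in HC in excitatory-neuron-like nuclei (log2 fold 1.34 ± 0.32), and 130 ± 101 against 55.4 ± 28.3 in inhibitory-neuron-like nuclei (1.39 ± 0.39). In astrocyte-like nuclei it was at 240 ± 193 against 74.9 ± 47.6 CPM (1.63 ± 0.48) and in oligodendrocyte precursors at 246 ± 49.7 against 95.0 ± 67.3 (1.30 ± 0.35). Over all genes its adjusted p by edgeR lay between 0.0881 and 0.320 in these types. APOE passed adjusted over the list alone in astrocyte-like and microglia-like nuclei, with the opposite folds given above. ADAMTS4, a protease of oligodendrocytes, did so in oligodendrocyte-like nuclei (-0.82 ± 0.21, 43.7 ± 12.5 against 75.5 ± 17.4 CPM) and APH1B, a subunit of gamma-secretase, in inhibitory-neuron-like nuclei (-0.66 ± 0.18). These genes were not refitted with donors left out, apart from APOE.

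Neuropeptides and secreted factors went both ways in excitatory-neuron-like nuclei, where the list did not pass by camera but did by fry in either direction (adjusted p = 0.00558), and 7 of its 15 members passed adjusted over the list alone. VGF was at 15.8 ± 9.86 CPM in AD and 43.7 ± 33.0 in HC (-1.83 ± 0.40), the growth factor BDNF at 14.2 ± 3.14 against 28.9 ± 9.003 (-1.03 ± 0.23), and the pituitary peptide ADCYAP1 at 7.45 ± 3.76 against 15.4 ± 5.40 (-1.29 ± 0.29). CARTPT was at -2.38 ± 0.68 and the pentraxin NPTX2, which gathers glutamate receptors at synapses, at -1.40 ± 0.46. Its relative NPTX1 was higher, at 190 ± 82.3 against 96.4 ± 11.7 CPM (0.88 ± 0.20), and so was the opioid precursor PDYN (1.53 ± 0.43). Over all genes the adjusted p of these 7 lay between 0.0753 and 0.219 (edgeR). In oligodendrocyte-like nuclei, NDRG1 (0.76 ± 0.18), DDIT4 (1.53 ± 0.35) and P4HA1 (-0.93 ± 0.29) passed adjusted over the list of hypoxia response genes alone, and the autophagy gene MAP1LC3A (-1.05 ± 0.25) and the lysosomal lipase LIPA (-0.53 ± 0.15) over that of lysosome and autophagy genes.

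Some clusters came almost alone from 1 donor. In microglia-like nuclei these were those given above. In astrocyte-like nuclei they were clusters of 713 nuclei (92.8% from AD 3), 729 (98.5% from HC 4) and 1667 (96.6% from HC 2). Of the 4 unnamed clusters, the one of 1667 shallow nuclei held 2.16 ± 1.96% of the kept nuclei in AD and 3.46 ± 2.72% in HC (exact permutation p = 0.310). The other 3 were of 407 nuclei, all from HC 4 (HC mean 1.26 ± 3.07%), of 69, 98.6% from HC 4 (0.0110 ± 0.0268% in AD and 0.210 ± 0.514% in HC), and of 29 with cell cycle transcripts, all from AD 3 (AD mean 0.0529 ± 0.129%).

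KLF15 and NFKBIA, which rose in oligodendrocyte-like nuclei, are known targets of the glucocorticoid receptor, and the hypothesis was tested that a glucocorticoid response may be part of the change, with 13 other textbook targets listed after the called genes were seen. In the precursors 13 of 13 were above 0 (median log2 fold 0.67 ± 0.12; camera p = 5.19e-10, and p = 0.0169 with an estimated correlation), and p stayed under 0.05 with any 1 donor left out (0.00225 to 0.0341 with an estimated correlation). In camera with an estimated correlation this call ended with the mitochondrial share as a covariate (median 0.47 ± 0.13, p = 0.0647) or log2 median UMIs (0.38 ± 0.12, p = 0.0517). The medians were smaller, with 1 degree of freedom fewer. In oligodendrocyte-like nuclei 11 of 13 were above 0 (median 0.57 ± 0.25; camera p = 1.06e-07, and p = 0.0528 with an estimated correlation), which leaves it undecided there, with 0.54 ± 0.24 (p = 0.114) and 0.38 ± 0.25 (p = 0.0892) under these covariates. Without HC 4 the median there was 1.11 (p = 0.0170) and without AD 2 0.74 (p = 0.0141), both with an estimated correlation. Singly 0 of the 13 passed over all genes by edgeR in either type, with FKBP5 at 2.25 ± 0.48 (adjusted p = 0.0677) and 1.31 ± 0.40 (adjusted p = 0.303) and DDIT4 at 1.53 ± 0.35 and 0.93 ± 0.33; at an unadjusted p under 0.05 there were 8 and 6, and DESeq2 and voom were not counted on this list.

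The mean log2 CPM of these targets was compared in each of the 7 types by exact permutation, and none passed after adjustment. It was 6.01 ± 0.558 in AD and 5.11 ± 0.440 in HC in oligodendrocyte-like nuclei (0.90 higher, exact p = 0.0195). The differences were 0.85 in the precursors (exact p = 0.0238), 0.44 in excitatory-neuron-like (p = 0.0411), 0.89 in microglia-like (p = 0.0433) and 1.30 in mural or fibroblast-like nuclei (p = 0.0286), with an adjusted p of 0.0606 for each of these 5. They were 0.29 in inhibitory-neuron-like (adjusted p = 0.149) and 0.30 in astrocyte-like nuclei (adjusted p = 0.340, exact permutation). Within groups, the level in oligodendrocyte-like nuclei of the 12 donors had r = -0.65 with log2 median UMIs (permutation p = 0.0502; rho = -0.60, permutation p = 0.0405; r = -0.47 without the 2 farthest donors; adjusted p = 0.129) and r = 0.58 with the mitochondrial share (permutation p = 0.0960; rho = 0.61, permutation p = 0.0429; r = 0.36; adjusted p = 0.129). In the precursors r was -0.56 (permutation p = 0.0965; rho = -0.62, permutation p = 0.0382; r = -0.40; adjusted p = 0.129) and 0.51 (permutation p = 0.140; rho = 0.55, permutation p = 0.0728; r = 0.35; adjusted p = 0.140), a family of 4 relations of which none passed. In both types AD 2 and AD 4 lay in the HC range, and HC 2, HC 3 and HC 4 in the AD range. So did HC 6 in precursors. Depth and RNA quality stay open beside the hypothesis. What else raises these targets was not tested. The sources used here give no hormone levels.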
